A study of Mus musculus with 9 samples.

How the data were processed

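Whole mouse embryos at 9.5 days post coitum were profiled on 9 Affymetrix arrays in 5 genotype groups, per the labels: 2 arrays homozygous for a targeted Notch1 allele (called Notch1 null here), 1 array heterozygous for it, 2 wild type, 2 heterozygous for a targeted Dll3 allele and 2 homozygous for it (Dll3 null). The labels do not say whether replicates are single embryos or separate litters, so p-values measure only the spread between these arrays, which may be partly technical.

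The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes, with no version given. The deposited values are linear ratios: of 22690 probe sets, 19847 (87.5%) have a median of exactly 1 over the 9 arrays, 19 lie below 1 by at most a rounding tolerance of 0.002, 2824 lie further below 1, and 0 have a median above 1. Each probe set was thus divided by 1 number of its own, read here as its median or, for the dimmest, a floor; no source used here states this step. A constant divisor leaves fold changes between arrays as they were but removes the absolute level. A filter by mean level, a trend of spread with level and the choice of the brightest probe set per gene, all planned before the data were examined, could therefore not be applied, and no value here says whether a transcript was detected.

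Ratios were converted to log2 without a pseudocount. After 64 control probe sets were set aside, 22626 were tested. Of these 20380 carry 1 gene symbol in the platform annotation, covering 12393 genes, 691 carry several and 1555 none; probe sets with several or no symbols were tested but not named. Symbols were compared through gene identifiers with a RefSeq table of assembly GRCm38.p6, which changed 0 of them. No genome build is named in the sources used here, so no coordinates are given. All 9 columns were used, 0 pairs of arrays were identical, and 0 values were missing.

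Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with 1 mean per genotype over all 9 arrays, which gave 4 residual and 5.42 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each of 7 comparisons, and an adjusted p under 0.05 is called changed. Errors are standard errors of that fit. The single Notch1 heterozygous array is assumed to vary like the arrays of the other groups. Probe sets of a gene were averaged for tests of 27 gene lists fixed before the data were examined; 766 of 880 listed genes (with a list of sex-linked genes) were measured. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. No list call held with an estimated correlation, and that adjusted p stands beside each call. With an estimated correlation camera uses only the 4 residual degrees of freedom, which the preset form does not. A call lost there therefore does not by itself show that correlation between genes accounts for it.

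The genes named are, for each null genotype against wild type, the 10 with the highest and the 10 with the lowest fold change among those changed with arrays that do not overlap, and 5 each way for the other comparisons, filled up to 5 by lowest p where fewer passed. A fixed set of Notch pathway and segmentation genes, sex-linked genes and the 2 to 4 members of lowest p in each list described were added.

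The procedure was tested on simulated data with 200 changed probe sets among 22626. For Notch1 null against wild type, 26.9% of probe sets changed by 0.5 on the log2 scale were called, 99.5% of those changed by 1 and 100% of those changed by 2; for the single Notch1 heterozygous array the figures were 11.4%, 91.5% and 100%, and for Dll3 null 28.9%, 98.5% and 100%. Unchanged probe sets called averaged 13.7, 10 and 12.3 per run. Over 3 runs, changed probe sets called at these sizes of change numbered 54, 200 and 198 for Notch1 null. They numbered 23, 184 and 198 for Notch1 het and 58, 198 and 198 for Dll3 null. In each comparison unchanged probe sets were thus a larger share of calls than the adjusted p threshold allows. In these simulations that threshold understated the share of false calls. On 12393 genes, a list shifted by 0.3 was called in 3 of 3 runs, with 0 calls of other lists. Genes were simulated as independent, so these runs do not test how correlation between genes affects the list calls.

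Alternatives were other scalings, robust and weighted fits, fits of only the groups compared, replicate number as a block, averaged probe sets, other thresholds and leaving out each array. Added after the data were seen were embryo sex as a covariate, sex-linked or floor-divided probe sets left out, the probe set with the largest SD per gene, and fits of only the wild-type and Notch1 arrays or only the Dll3 arrays, which does not remove the differences in spike-in level among the former. Replicate numbers were checked for pairing: the differences between replicates 1 and 2 correlated above 0.1 in 1 of 6 pairs of groups, with a range from -0.10 to 0.16, so the numbers were not treated as pairs.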

Results

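Transcript levels were measured in whole embryos at 9.5 days post coitum carrying targeted alleles of 2 genes of the Notch pathway, the receptor gene Notch1 and the ligand gene Dll3. Values from whole embryos do not tell a change of expression per cell from a change in the amount of a tissue. Each of 4 groups had 2 arrays and the Notch1 heterozygous group had 1; this small number limits the precision of every value. Replicate arrays correlated over probe sets at 0.804 in Notch1 null, 0.765 in wild type, 0.673 in Dll3 het and 0.651 in Dll3 null. Arrays of different groups ranged from 0.426 (Notch1_null replicate 2 with Dll3_het replicate 2) to 0.743 (Dll3_het replicate 1 with Dll3_null replicate 2). The Dll3 replicates were thus no more alike than some arrays of the other Dll3 genotype. The 2811 tested probe sets with a median further below 1 than rounding can raise the correlation of any 2 arrays. These values are therefore not a measure of replicate agreement alone. Levels of Xist, expressed from the inactive X chromosome, and Eif2s3y, on the Y chromosome, gave a female pattern in replicate 1 of Notch1 null, Notch1 het, Dll3 het and Dll3 null and a male pattern in the other 5 arrays, including both wild types.

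The targeted genes were examined first. Notch1 signal was higher, not lower, in the arrays labelled Notch1 null: 1 of its 2 probe sets was 1.63-fold above wild type (log2 0.71 ± 0.13 SE, adjusted p = 0.0138) and the other 1.52-fold (log2 0.60 ± 0.23, adjusted p = 0.142). The Notch1 call of the former ended without Notch1_null replicate 2 (adjusted p = 0.118), without wild_type replicate 1 (0.0915) and without wild_type replicate 2 (0.0662). The single Dll3 probe set was 1.21-fold lower in Dll3 null (log2 -0.27 ± 0.12, adjusted p = 0.486) and did not pass the test. The position of these probes relative to the deleted sequence is not given in the sources used here, so neither result checks the labels; directions below refer to the arrays as labelled.

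Some poly-A control RNAs, which are added to a sample before labelling, separated the arrays. The dap control was 10.1-fold higher in the 5 wild-type and Notch1 arrays than in the 4 Dll3 arrays, and thr was 2.92-fold higher; phe (1.68-fold) overlapped between these arrays and lys (1.43-fold) nearly did. Among the former, the mean dap ratio was 6.61 and 9.20 in wild type, 5.26 and 2.62 in Notch1 null and 1 in Notch1 het, so dap also parts the Notch1 groups from wild type and from each other. The hybridisation control cre, added later, differed by 1.00-fold.

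**Figure D1:**
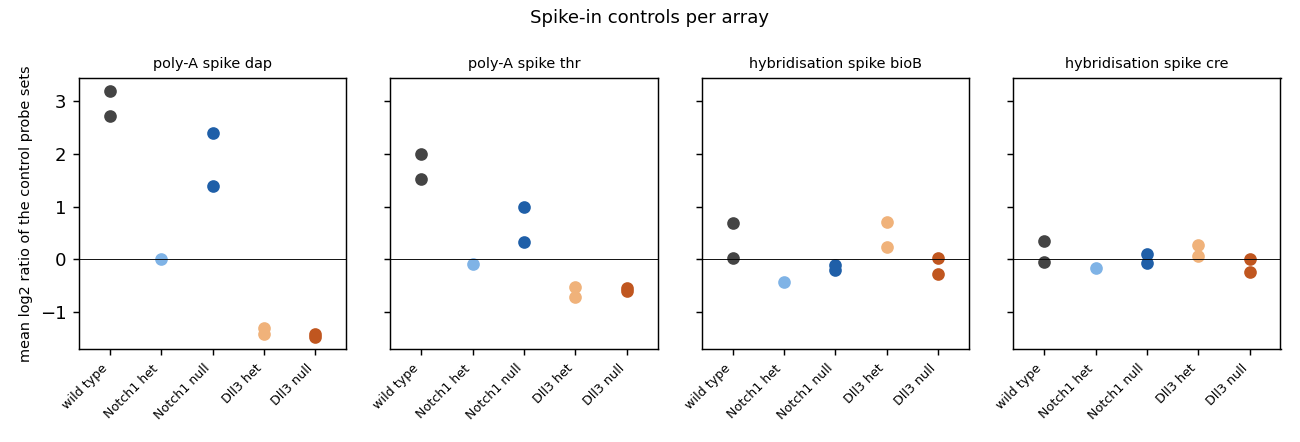
Mean log2 ratio of control probe sets for 2 poly-A and 2 hybridisation controls, 1 point per array, by genotype. All 4 Dll3 arrays lie below the 5 other arrays for dap, and the cre control shows no such separation.

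Notch1 null was compared with wild type to ask which transcripts follow loss of the receptor. Many genes that respond to low oxygen or belong to glycolysis rose, 30 of 46, while as a list they had an adjusted p = 0.187 with an estimated correlation. The highest changes were Ddit4, an inhibitor of mTOR signalling induced by stress (6.79-fold, log2 2.76 ± 0.26 SE, adjusted p = 0.0011), Ier3, an early response gene (6.65-fold), Adm, which encodes the vasodilator adrenomedullin (5.88-fold), Stc2 (5.85-fold), the phosphofructokinase gene Pfkp (5.37-fold), Vldlr (5.29-fold), Ppp1r3c, a regulator of glycogen synthesis (4.82-fold), Luc7l2 (4.42-fold), the glucose transporter gene Slc2a3 (4.33-fold) and the transcription factor gene Bhlhe40 (log2 2.00 ± 0.15). Luc7l2 had 2 of its 5 probe sets changed this way. Adjusted p of these genes lay at or below 0.0101; the Luc7l2 call ended in 4 of 15 alternatives, with an adjusted p up to 0.102 without Notch1_null replicate 2. Quantile normalization lowered log2 changes to 2.16 for Ddit4, 1.93 for Adm, 1.88 for Stc2, 1.69 for Pfkp, 1.64 for Vldlr, 1.54 for Ppp1r3c, 1.44 for Luc7l2 and 1.32 for Bhlhe40.

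Of 46 measured genes of hypoxia and glycolysis, 30 rose, 0 fell and 16 did not pass (34 rose when adjusted over the list alone), with a median log2 change of 0.76. Averaged over probe sets, Bnip3, a mitochondrial autophagy gene induced by hypoxia, rose 3.58-fold (log2 1.84 ± 0.09 SE), Stc2 3.24-fold and Slc2a3 3.17-fold. Camera gave an adjusted p of 6.33e-34 for the list, and the adjusted p = 0.187 with an estimated correlation. The rise was seen in both Notch1 null arrays; 22 genes of the list still rose without Notch1_null replicate 2.

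Some genes of neurons and neural progenitors fell. Hes5, a transcriptional target of Notch in neural progenitors, was 3.26-fold lower at 1 probe set (log2 -1.70 ± 0.12 SE, adjusted p = 0.000375) and 2.25-fold lower at its other probe set. Tubb3, a tubulin of neurons, was 4.19-fold lower, Fabp7, a lipid binding protein of radial glia, 3.95-fold lower, the neuronal gene Stmn2 2.92-fold lower and Ckb, brain creatine kinase, 2.92-fold lower. Of 64 neurogenesis genes, 24 fell, 1 rose and 39 did not pass (27 fell and 1 rose adjusted over the list alone), with Neurog2, a proneural factor, 2.06-fold lower and Stmn3 2.25-fold lower; camera gave an adjusted p of 1.07e-06, and the adjusted p = 0.187 with an estimated correlation. Of 41 neural progenitor genes, 10 fell and 3 rose (13 and 3 adjusted over the list alone), among them Pou3f3 (2.04-fold lower) and Sox3 (1.64-fold lower), with a camera adjusted p of 0.0174 and an adjusted p = 0.187 with an estimated correlation. Both wild-type arrays had the highest neurogenesis means of all 9 arrays (0.15 and 0.10, the next being 0.06 in Dll3_het replicate 2), so part of that fall is shared by every other group. The wild-type arrays were also highest for neural progenitors, where Dll3 null lay close to them (mean log2 difference -0.01).

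Other genes with the lowest fold changes were Cbl, a ubiquitin ligase gene (6.33-fold lower), Ago2, of RNA silencing (4.53-fold lower), Akap9 (3.36-fold lower), Rbbp4 (3.35-fold lower) and Pdap1 (3.10-fold lower). For Akap9, Rbbp4 and Pdap1 only 1 of their probe sets changed, and the Pdap1 call ended in 7 of 15 alternatives, with an adjusted p up to 0.217 without Notch1_null replicate 2. Cbl, Ago2 and Akap9 also fell in Dll3 null, Dll3 het and Notch1 het against the same wild-type arrays.

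Among Notch target genes, 4 of 18 fell and 0 rose, and 4 fell adjusted over the list alone: Hes5, Id4 (2.18-fold lower), Nrarp, a feedback inhibitor of Notch (1.83-fold lower), and Ccnd1 (1.54-fold lower). As a list they did not pass camera (adjusted p = 0.205, and the adjusted p = 0.504 with an estimated correlation), while fry, which asks whether the genes move 1 way on balance, gave an adjusted p of 0.00397. Both wild-type arrays lay above all 7 others for this list (-0.02 and 0.02, the next -0.07), and against Notch1 het 0 of 18 passed (camera adjusted p = 0.824). Of 3 Heyl probe sets, 1 fell (log2 -0.60 ± 0.10). Of 15 alternatives 3 ended this Heyl call (adjusted p up to 0.0873), and 3 and 4 ended the calls of the 2 Nrarp probe sets (up to 0.0853 and 0.126). The log2 changes of Hes1 (-0.18 ± 0.13), Hey1 (-0.37 ± 0.16), Hey2 (-0.05 ± 0.13), Hes7 (0.13 ± 0.12), Dll1 (-0.02 ± 0.12), Mesp2 (-0.28 ± 0.14) and Lfng (-0.33 ± 0.11 and -0.06 ± 0.14 at its 2 probe sets) did not pass.

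Of 30 genes of somite derivatives, 9 fell and 1 rose, with the same counts adjusted over the list alone. Uncx, a marker of the posterior part of each somite, fell 2.41-fold (log2 -1.27 ± 0.11 SE), Aldh1a2, which makes retinoic acid, 2.02-fold, Pax1, of the sclerotome, 1.88-fold and Tcf15 1.61-fold. The list's camera adjusted p was 0.0174, and the adjusted p = 0.374 with an estimated correlation. Both wild-type arrays (0.11 and 0.01) again lay above all 7 others, of which the highest was -0.05. Of 48 cell cycle genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone), led by Ccne1, cyclin E1 (2.33-fold lower), with a camera adjusted p of 0.0174 and an adjusted p = 0.504 with an estimated correlation. Of 33 segmentation clock and presomitic mesoderm genes, 1 rose, Cyp26a1, and 2 fell, Nrarp and Snai1 (5 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.241.

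Heart and vessel genes rose in part. Of 46 cardiac muscle genes 6 rose and 1 fell (7 and 1 adjusted over the list alone): Ankrd1 rose 2.29-fold (log2 1.19 ± 0.11 SE), the myosin gene Myh7 2.12-fold and the titin gene Ttn 1.88-fold, while Tbx2, a repressor of chamber muscle genes, was 1.60-fold lower. Camera gave an adjusted p of 0.00069, and the adjusted p = 0.187 with an estimated correlation. Of 40 endothelial genes 7 rose and 0 fell (7 and 1 adjusted over the list alone), including Kdr, the main VEGF receptor (1.82-fold), and Sox17 (1.76-fold), with a camera adjusted p of 0.00398 and an adjusted p = 0.504 with an estimated correlation. Of 27 p53 and apoptosis genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.0451 and an adjusted p = 0.497 with an estimated correlation; the members that rose were Ddit4, Polk, a DNA polymerase, and Apaf1. This p53 call rests on members of other lists, Ddit4 among them: without them its mean fell from 0.17 to 0.07 and the adjusted p was 0.133. It also ended with median centring (0.0571), quantile normalization (0.0851) and the probe set of largest SD per gene (0.0602). Without wild_type replicate 1 the calls of somite derivatives (adjusted p = 0.112), endothelium (0.0855), cell cycle (0.119) and p53 and apoptosis (0.0855) ended. Without Notch1_null replicate 2 those of cell cycle (0.0735) and p53 and apoptosis (0.205) ended. By fry, adjusted p was 0.00397 for hypoxia and glycolysis, 0.00623 for neurogenesis, 0.00122 for neural progenitors, 0.0097 for somite derivatives and 0.0175 for cardiac muscle, while endothelium (0.224), p53 and apoptosis (0.162) and cell cycle (0.0505) did not pass it. Ribosomal protein genes were lower by fry (adjusted p = 0.0097), with 0 of 37 passing singly. Camera did not call them (adjusted p = 0.122, and 0.504 with an estimated correlation).

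In all, 783 probe sets were higher and 1356 lower in Notch1 null, together 2139. The count was 879 without Notch1_null replicate 1, 306 without Notch1_null replicate 2, 610 without wild_type replicate 1 and 398 without wild_type replicate 2, and 969 after quantile normalization. It was 1641 with embryo sex in the fit, and 1717 among the 5 wild-type and Notch1 arrays. Both Notch1 null arrays lie below both wild-type arrays in dap, so preparation that follows this control and genotype cannot be told apart by these counts.

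**Figure D2:**
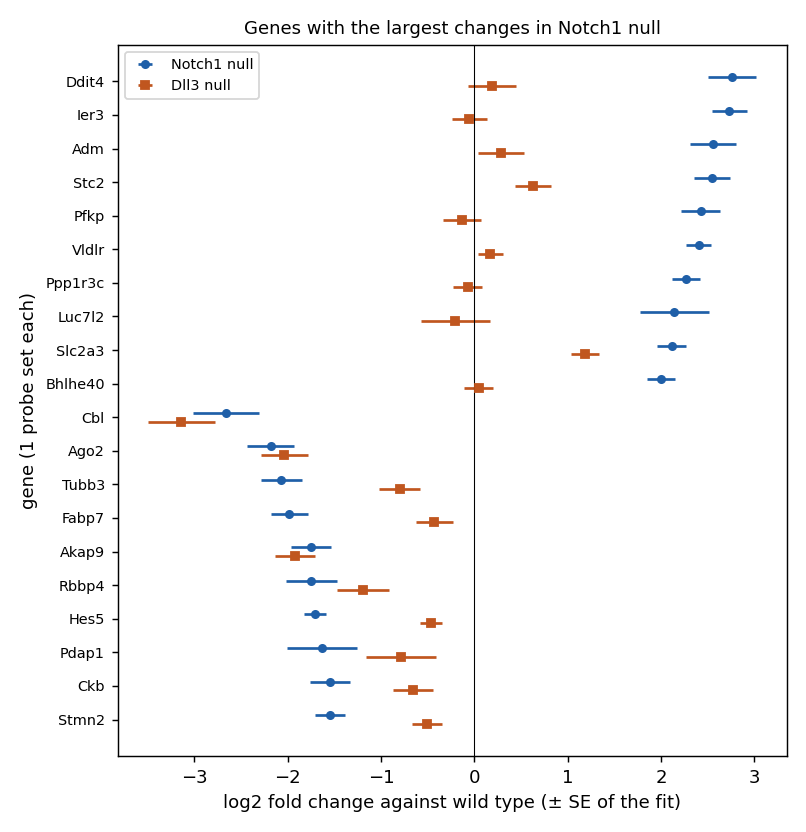
Log2 fold change against wild type with the standard error of the fit, for the 10 genes highest and the 10 lowest in Notch1 null (circles), with Dll3 null at the same probe sets (squares). Ddit4 lies at 2.76 in Notch1 null, and Cbl, Ago2 and Akap9 are lower in both genotypes.

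**Figure D3:**
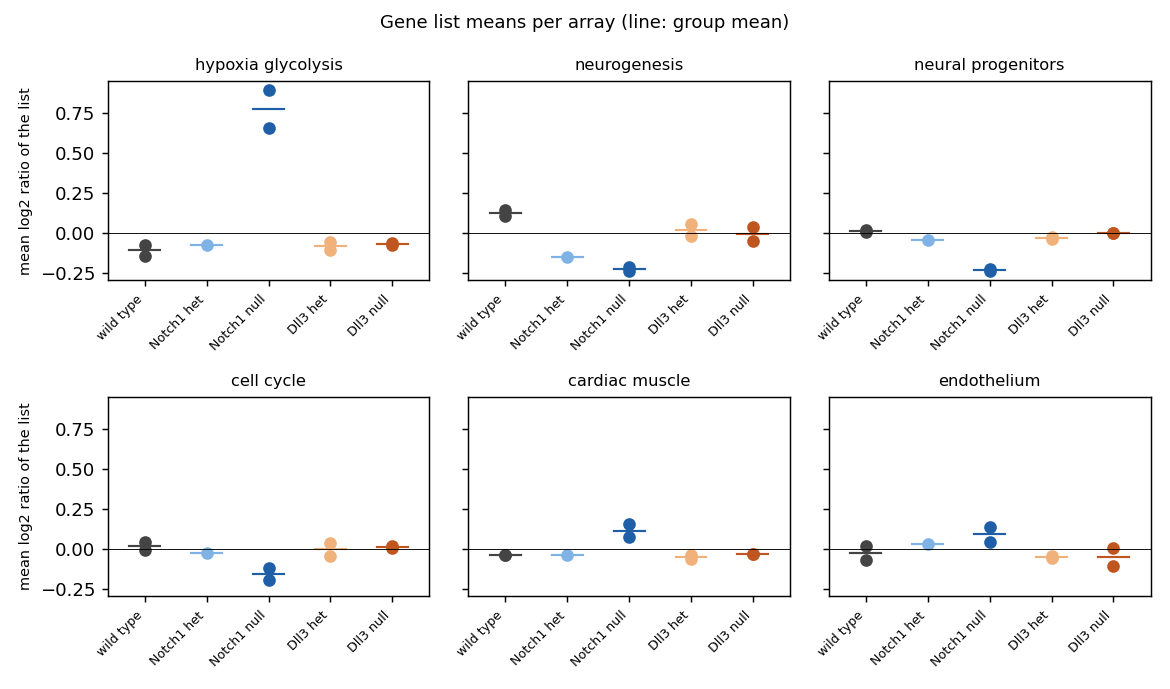
Mean log2 ratio of 6 gene lists on each array, 1 point per array with a line at the group mean, by genotype. Both Notch1 null arrays lie above the 7 other arrays for hypoxia and glycolysis and below them for neurogenesis.

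Dll3 null was compared with wild type to ask what follows loss of the ligand. Few transcripts changed. Slc2a3 rose 2.27-fold (log2 1.18 ± 0.15 SE, adjusted p = 0.0403) and Tfrc, the transferrin receptor, 2.09-fold (adjusted p = 0.0403). Cbl was 8.81-fold lower (log2 -3.14 ± 0.36, adjusted p = 0.0296), Ago2 4.10-fold, Akap9 3.78-fold, Ttc28 2.64-fold, the aminopeptidase gene Npepps 2.54-fold, Eif4ebp2, a repressor of translation, 2.51-fold, Ccnd2, cyclin D2, 2.18-fold, Mtdh 2.15-fold, Pbrm1 2.12-fold and Ppp1r14a 2.09-fold lower. Each of these genes with more than 1 probe set had 1 changed, except Slc2a3 with 2 of 4. Each named call ended in 6 (Ttc28) to 13 (Ppp1r14a) of 14 alternatives, and the log2 change of Cbl was -2.49 without Dll3_null replicate 1 and -3.79 without Dll3_null replicate 2. Prkci, Kansl1 and Eif2d, added by lowest p, were higher in Dll3 null but did not pass.

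No gene of the lists of Notch targets, segmentation clock or somite derivatives passed in Dll3 null. Averaged over probe sets, only 1 of all 12393 genes passed in this comparison, so this does not show that these lists were unchanged. Adjusted over the list alone, 1 was higher and 1 lower among Notch targets, and 1 and 1 in the segmentation clock. Among somite derivatives 0 were higher and 4 lower in that way (camera adjusted p = 0.0534). The log2 changes were -0.46 ± 0.12 and -0.21 ± 0.12 SE for Hes5 at its 2 probe sets, -0.78 ± 0.12 for Uncx (adjusted p = 0.0698), -0.27 ± 0.14 for Mesp2 and 0.17 ± 0.12 for Hes7. By camera, 64 neurogenesis genes were lower on balance, with a median of -0.12 and an adjusted p of 0.00015, though 0 passed singly and 4 were lower adjusted over the list alone; the adjusted p = 0.638 with an estimated correlation. The wild-type arrays stand above all others for this list, and Dll3 null did not differ from Dll3 het in it (camera adjusted p = 0.491). The 49 neural crest genes (median -0.08, 6 lower adjusted over the list alone) and 13 anterior Hox genes (median -0.15, 1 lower) had camera adjusted p of 0.0229, and the adjusted p = 0.638 for each with an estimated correlation. Both calls ended without wild_type replicate 1 (0.200 each), without Dll3_null replicate 1 (0.344 and 0.226), with embryo sex in the fit (0.151 and 0.0755) and with members of other lists left out (0.558 and 0.103), and the Hox call also with the probe set of largest SD per gene (0.0838).

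In Dll3 null 4 probe sets were higher and 16 lower, together 20, by limma, and 2307 had an unadjusted p under 0.05 where chance gives 1131. The count was 0 with only the arrays of both groups fitted, 2 with embryo sex in the fit, 1 without wild_type replicate 1, 0 without wild_type replicate 2, 7 without Dll3_null replicate 1 and 49 without Dll3_null replicate 2. It was also 2 without either Notch1 null array and 0 without either Dll3 het array, which enter through the shared estimate of spread. Because dap separates all Dll3 arrays from all wild-type arrays, preparation and genotype cannot be told apart by these counts.

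Both null genotypes were then set side by side, to ask whether receptor and ligand loss change the same transcripts. Fold changes against wild type correlated across probe sets, which are not independent replicates, at Pearson 0.46 and Spearman 0.45. Unchanged groups simulated against shared controls gave 0.50, from the shared wild-type arrays alone. That simulation holds no genotype effects, which add to the spread, so the observed correlation cannot be weighed against it directly. The covariance was 0.0286, which exceeds the simulated one by 0.0185. Among changed probe sets 3 were higher and 15 lower in both, where independent lists give 0.138 and 0.959. The highest of 100 simulations gave 1 and 1. These held no changed probe sets, so they do not show what overlap the shared wild-type arrays give here. Part of the excess may come from the shared controls, which were not split because each part would hold 1 array. With each null set against its own heterozygotes, with no array shared, the correlation was -0.06. Dll3 null and Dll3 het differed at 0 probe sets, and Notch1 het is 1 array. This value therefore does not show whether the null genotypes share a response.

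Tested directly, Notch1 null exceeded Dll3 null in the hypoxia and glycolysis genes, of which 31 of 46 were higher and 0 lower (34 and 0 adjusted over the list alone), with a camera adjusted p of 1.83e-39 and an adjusted p = 0.191 with an estimated correlation. Ier3 was 6.89-fold higher (log2 2.78 ± 0.19 SE), Ddit4 5.97-fold, Pfkp 5.88-fold, Luc7l2 5.08-fold and Ppp1r3c 5.07-fold. Fabp7 was 2.94-fold lower, Hnrnpl 2.70-fold, Med29 2.64-fold, the gap junction gene Gja4 2.47-fold and Tubb3 2.40-fold lower. Of 14 alternatives 4 ended the Luc7l2 call (adjusted p up to 0.119 without Notch1_null replicate 2) and 4 the Tubb3 call (up to 0.0923 without Notch1_null replicate 1). Quantile normalization lowered log2 changes to 1.96 for Ddit4, 1.84 for Pfkp, 1.64 for Ppp1r3c and 1.59 for Luc7l2, which was also 1.59 without Dll3_null replicate 1 and 3.10 without Dll3_null replicate 2. Hes5 was 2.36-fold lower at 1 probe set (log2 -1.24 ± 0.12, adjusted p = 0.0019), and Uncx 1.40-fold lower (adjusted p = 0.0475), though 13 of 14 alternatives ended the Uncx call, with an adjusted p up to 0.282 without Notch1_null replicate 2. Notch1 itself was 1.92-fold higher at 1 probe set (adjusted p = 0.00763) and 1.95-fold at the other (adjusted p = 0.042). The former call ended with only these 4 arrays fitted (0.0716), without Notch1_null replicate 2 (0.0867) and without Dll3_null replicate 1 (0.0531). The latter ended in 11 of 14 alternatives, with an adjusted p up to 0.288 without Notch1_null replicate 2.

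Other lists also differed between the null genotypes. Neurogenesis genes were lower in Notch1 null, 13 of 64 with 1 higher (16 and 1 adjusted over the list alone), Tagln3 1.80-fold, with a camera adjusted p of 0.0025 and an adjusted p = 0.354 with an estimated correlation. So were neural progenitor genes, 8 of 41 with 2 higher (12 and 2), Sox3 1.87-fold lower, at 0.0106 and an adjusted p = 0.216 with an estimated correlation. Cell cycle genes followed, 5 of 48 lower and 0 higher (7 and 0), Ccne1 1.78-fold lower, at 0.00518 and an adjusted p = 0.375 with an estimated correlation. Stress genes were higher, 8 of 36 with 2 lower (12 and 5), Chac1 3.67-fold, at 0.00201 and an adjusted p = 0.354 with an estimated correlation. Higher on balance were also cardiac muscle (5 of 46 higher, 0 lower; Ankrd1 1.93-fold; camera adjusted p 0.00045, and the adjusted p = 0.191 with an estimated correlation) and endothelium (6 of 40 higher, 1 lower; Sox17 1.89-fold; 0.000422, and the adjusted p = 0.354 with an estimated correlation). For endocardial cushions 4 of 21 were higher and 0 lower, with Tgfb2 1.78-fold higher, a camera adjusted p of 0.0168 and an adjusted p = 0.354 with an estimated correlation. For p53 and apoptosis 2 of 27 were higher and 2 lower, with Polk 1.53-fold higher, a camera adjusted p of 0.0192 and an adjusted p = 0.354 with an estimated correlation; with members of other lists left out the mean fell from 0.17 to 0.07 and the call ended (0.0947). Primitive red cell genes were higher on balance (mean 0.13, 25 positive and 17 negative), although 0 of 42 passed as higher and 1 as lower, Bpgm, with a camera adjusted p of 0.0168 and an adjusted p = 0.656 with an estimated correlation. Without Notch1_null replicate 2 the calls of endocardial cushions (0.0687), p53 and apoptosis (0.150) and primitive red cells (0.244) ended. Without Dll3_null replicate 1 that of endocardial cushions ended (0.0539), and without Dll3_null replicate 2 primitive red cell genes turned to a mean of -0.0851.

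In all 557 probe sets were higher and 741 lower. With median centring 610 were higher and 595 lower, and after quantile normalization 292 and 276, so which direction had more depended on scaling. Together 1298 changed in the main fit. The count fell to 9 with only these 4 arrays fitted, to 57 without Notch1_null replicate 2 and to 271 without Dll3_null replicate 1, and was 488 without Notch1_null replicate 1, 862 without either wild-type array and 568 after quantile normalization. The dap control separates these groups too, so preparation and genotype cannot be told apart by these counts.

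The heterozygotes were compared with wild type to ask whether 1 altered allele changes expression. In the single Notch1 heterozygous array Hes5 was 1.85-fold lower (log2 -0.89 ± 0.13 SE, adjusted p = 0.0165), Id4 2.40-fold, Stmn2 2.53-fold, Tubb3 3.54-fold and Fabp7 2.70-fold lower, averaged over probe sets. Of 64 neurogenesis genes 10 fell and 1 rose (20 and 2 adjusted over the list alone), with a camera adjusted p of 1.32e-05 and an adjusted p = 0.392 with an estimated correlation. The 46 hypoxia and glycolysis genes had a mean log2 change of 0.03. Ribosomal protein genes were lower on balance, 1 of 37 passing, Rpl14 (1.55-fold lower; 5 lower adjusted over the list alone), with a camera adjusted p of 6.6e-05 and an adjusted p = 0.392 with an estimated correlation. Cholesterol synthesis genes were lower as well, 1 of 19 passing, Tm7sf2 (2.03-fold lower; 4 lower and 1 higher adjusted over the list alone), at 0.00082 and an adjusted p = 0.708 with an estimated correlation. Of segmentation clock genes 0 of 33 passed (3 higher adjusted over the list alone), with a median of 0.17, a camera adjusted p of 0.0143 and an adjusted p = 0.565 with an estimated correlation; the call ended without wild_type replicate 1 (0.0944). Of 36 stress genes 0 passed, with a median of -0.15, a camera adjusted p of 0.0121 and an adjusted p = 0.590 with an estimated correlation. By probe set Car4 (3.39-fold), Sfxn1 (2.93-fold), Celsr1 (2.91-fold), Sh3glb1 (2.81-fold) and Kansl1 (2.60-fold) were highest and Cbl (9.21-fold), Csnk2a1 (7.41-fold), Evi5 (5.75-fold), Ago2 (5.63-fold) and Hnrnpab (5.60-fold) lowest. Of 14 alternatives 10 ended the Csnk2a1 call (adjusted p up to 0.173 without wild_type replicate 2), 8 the Hnrnpab call (up to 0.135 with only these arrays fitted) and 3 to 5 each of the others, and the log2 change of Csnk2a1 was -2.30 with embryo sex in the fit. In all 224 probe sets were higher and 400 lower, together 624. This rests on 1 array, and the count was 0 without either wild-type array, 7 with only these arrays fitted, 36 with embryo sex in the fit, 198 among the wild-type and Notch1 arrays, 268 without either Notch1 null array, 334 without either Dll3 het array and 199 after quantile normalization. The Notch1 het array lies below both wild-type arrays in dap, so preparation and genotype cannot be told apart by these counts either.

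In Dll3 het, Tgfbr1, a TGF-beta receptor, was 2.40-fold higher (log2 1.26 ± 0.16 SE, adjusted p = 0.0283), Tfrc 2.37-fold, Top2b 2.20-fold, Supt20 2.19-fold and Prkci 2.06-fold higher, while Cbl was 5.18-fold, Rbbp4 3.23-fold, Ago2 3.08-fold, Akap9 2.58-fold and Irak1 2.43-fold lower. Each of these calls ended in 8 or 9 of 14 alternatives. In all 42 probe sets were higher and 68 lower, together 110. The count was 0 with embryo sex in the fit, 0 without wild_type replicate 2 or either Dll3 het array, 1 without wild_type replicate 1 or either Notch1 null array, 197 without either Dll3 null array, 4 with only these arrays fitted and 68 after quantile normalization. Dll3 het and wild type differ in dap as well, so preparation and genotype cannot be told apart by these counts.

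Each null was last compared with its own heterozygotes. Dll3 null and Dll3 het have similar dap levels, while Notch1 het lies below both Notch1 null arrays, so that preparation and genotype cannot be told apart by the count of changed probe sets for Notch1. Dll3 null and Dll3 het did not differ at any probe set: limma called 0, and 1201 had an unadjusted p under 0.05 where chance gives 1131. The probe sets of lowest p were Crbn, Actl11, Sem1, Cd24a and Hif1a, from 1.49 to 1.58-fold higher, and Tes3-ps, Itgb1, Aqr, Nup62 and Cldnd1, from 1.44 to 1.62-fold lower, all with an adjusted p of 0.897. Without Dll3_null replicate 2 the count was 17. The 42 genes of primitive red cells were lower on balance, with a median log2 change of -0.16 and a camera adjusted p of 7.33e-06, but 0 passed singly or adjusted over the list alone and the adjusted p = 0.996 with an estimated correlation; their mean turned to 0.03 without Dll3_null replicate 2.

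Against the Notch1 heterozygous array, Notch1 null again had higher Ddit4 (12.9-fold, log2 3.69 ± 0.31 SE, adjusted p = 0.00271), Adm (7.13-fold), the metallothionein gene Mt1 (6.79-fold), Ier3 (6.45-fold) and Vldlr (5.50-fold), and lower Polr2a (2.96-fold), Nynrin (2.81-fold), Psme3 (2.79-fold), Epop (2.68-fold) and Sf3a2 (2.61-fold). All 10 calls ended with only these 3 arrays fitted (adjusted p from 0.0658 to 0.170); of 14 alternatives 10 ended that of Sf3a2 and 4 each those of Mt1 and Nynrin. Quantile normalization lowered log2 changes to 3.07 for Ddit4, 2.16 for Adm and 1.64 for Vldlr. Of the hypoxia and glycolysis genes 22 of 46 rose and 0 fell (32 and 1 adjusted over the list alone), with a camera adjusted p of 6.76e-35 and an adjusted p = 0.235 with an estimated correlation. Of 36 stress genes 5 rose and 1 fell, Mt2 4.41-fold higher, with a camera adjusted p of 8.68e-06 and an adjusted p = 0.318 with an estimated correlation. Of 46 cardiac genes 4 rose and 0 fell, Nppa, atrial natriuretic peptide, 2.07-fold, at 0.00123 and an adjusted p = 0.235 with an estimated correlation. Of 19 cholesterol synthesis genes 2 rose, Tm7sf2 1.82-fold and Stard4 1.52-fold, at 0.00299 and an adjusted p = 0.653 with an estimated correlation; this call ended without Notch1_null replicate 1 (0.114). Of 37 ribosomal protein genes 0 passed, at 0.00884 and an adjusted p = 0.395 with an estimated correlation; this call ended with the probe set of largest SD per gene (0.151). Lists called in Notch1 null against wild type but not here were neurogenesis (1 of 64 lower, camera adjusted p = 0.599), neural progenitors (5 of 41 lower, 0.0731), somite derivatives (3 of 30 lower, 0.342), cell cycle (2 of 48 lower, 0.0731), endothelium (1 of 40 higher, 0.0937) and p53 and apoptosis (1 of 27 higher, 0.0811). Hes5 was 1.46-fold lower than in the heterozygote (log2 -0.55 ± 0.13, adjusted p = 0.0545) and did not pass. In all 193 probe sets were higher and 210 lower, together 403. The count was 0 with only these 3 arrays fitted, 105 with embryo sex in the fit, 88 among the wild-type and Notch1 arrays, 78 without Notch1_null replicate 1, 22 without Notch1_null replicate 2, 126 without either wild-type array, 191 without either Dll3 het array and 49 after quantile normalization.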

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

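The tests of probe sets of the same gene, of the spike-in separation, of embryo sex, of the other genotypes and of exchanged labels were chosen after the results they bear on were seen.

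The effects of the null genotypes, both against the same wild type, differed at 1298 probe sets by the direct limma contrast. The same contrast differed for 7 gene lists that also changed against wild type: hypoxia and glycolysis had a mean log2 difference of 0.84, neurogenesis -0.22, neural progenitors -0.23, cell cycle -0.17, endothelium 0.14, cardiac muscle 0.14 and p53 and apoptosis 0.17. With an estimated correlation none of these lists passed, with an adjusted p = 0.191 for hypoxia and glycolysis and for cardiac muscle, 0.216 for neural progenitors, 0.375 for cell cycle and 0.354 for the others. In control probe sets that no comparison used, the poly-A control dap was 10.1-fold higher in the wild-type and Notch1 arrays than in the Dll3 arrays.

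The rise of hypoxia and glycolysis genes in the arrays labelled Notch1 null had a mean log2 change of 0.88. A difference in preparation that follows the spike-ins is argued against, since Dll3 null, farther from wild type in dap, had a list mean of 0.0415, and Notch1 null lies between wild type and Notch1 het in dap but above both in the list (0.88 and 0.85). Embryo sex is argued against as well, since the mean was 0.91 with sex in the fit. Genotype remains a candidate explanation: among Dll3 null, Dll3 het and the single Notch1 het array the list mean farthest from 0 was 0.0415. Time between dissection and lysis stays open, because 8 immediate early genes had a median of 0.0207 with Egr1 higher (log2 0.98 ± 0.19 SE) and they can rise and fall within such a time.

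Of 112 probe sets changed against wild type in Dll3 null or Dll3 het, 70 changed the same way in Notch1 null and 46 in Notch1 het, and for 83 both wild-type arrays lay outside all 7 other arrays. The other probe sets of the same genes followed little. Taking the mean of the Dll3 null and Dll3 het changes, their median share was 0.215 of that of the called probe set, over 87 called probe sets. For those changed between Notch1 null and Dll3 null it was 0.544, in that contrast. The selections differ: 20 of 20 calls in Dll3 null and 109 of 110 in Dll3 het reached 1.5-fold, against 824 of 1298. Signals of single probe sets rather than whole transcripts are thus a candidate, not separated from this difference in selection. A preparation difference along the spike-ins cannot be told apart from other causes, since the Notch1 null change was 0.669 of the Dll3 change, with quartiles of 0.376 and 0.941, the Notch1 arrays also lie below wild type in dap, and the shared wild-type arrays add to that share. No biological explanation was tested, and strain or litter of the wild-type embryos is not given in the sources used here.

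Notch1 signal was higher in the arrays labelled Notch1 null at both of its 2 probe sets. These arrays held the lowest places for Hes5 and Nrarp in 4 of 4 cases, opposite to what an exchange with others predicts. Both genes had already been seen to fall in these arrays, so this is not an independent check of the labels. Neighbouring chromosome from another strain stays open: the 40 measured genes nearest to Notch1 had a median of -0.14, opposite in sign to Notch1 but apart from the median of all genes, -0.03, with 9 of the 40 lower and 1 higher against 1035 lower and 466 higher of 12393 genes. Probes outside the deleted sequence could give this signal, and that was not testable with the sources used here.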

How the results depend on the processing

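Alternatives that used embryo sex, floor-divided or sex-linked probe sets, the largest SD or the side of the spike-in separation were chosen after the data were seen. Filters by mean level, a trend with level and the brightest probe set per gene were not run, since ratios hold no level. Over 7 counts, 80 of 149 alternatives stayed within 1.5 times the value reported, and median centring, robust and weighted fits did so for all 7. These counts are totals of both directions. Median centring turned an excess of lower probe sets into an excess of higher ones for Notch1 null against Dll3 null and against Notch1 het. The 80 include alternatives for Dll3 null against Dll3 het, where a count of 0 stayed 0. They also include leaving out the single Notch1 het array, which cannot change the counts of comparisons without it. The cause of the changes was not tested, except that leaving out an array or fitting fewer arrays leaves fewer residual degrees of freedom. Signal over background is not known here, so its limit on precision is not either.

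For Notch1 null against wild type, 2139 became 969 after quantile normalization, 3308 at an adjusted p under 0.10 and 1197 at 1.5-fold or more, with 306 to 2139 when 1 array was left out. For Dll3 null against wild type, 20 became 0 with only the groups compared, 2 with the replicate block, 1 with probe sets averaged, 2 with sex and 66 at 0.10, and ranged from 0 to 49. For Notch1 null against Dll3 null, 1298 became 568 after quantile normalization, 9 with only the groups compared, 2317 at 0.10 and 824 at 1.5-fold, and ranged from 57 to 1298. For Dll3 het against wild type, 110 became 68 after quantile normalization, 4 with only the groups compared, 40 with the replicate block, 14 with probe sets averaged, 0 with sex and 569 at 0.10, and ranged from 0 to 197. For Notch1 het against wild type, 624 became 199 after quantile normalization, 7 with only the groups compared, 363 with the replicate block, 279 with probe sets averaged, 36 with sex, 198 within the wild-type and Notch1 arrays and 1477 at 0.10, and ranged from 0 to 543. For Notch1 null against Notch1 het, 403 became 49 after quantile normalization, 0 with only the groups compared, 150 with the replicate block, 105 with sex, 88 within the wild-type and Notch1 arrays and 1004 at 0.10, and ranged from 22 to 341. For Dll3 null against Dll3 het the count was 0, and 0 to 17 when 1 array was left out. What the replicate numbers stand for is not given, and in Notch1 null, Dll3 het and Dll3 null they follow embryo sex. Whether calls lost under the block reflect weaker effects was therefore not settled.

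The correlation of the null genotypes, 0.46, ranged from 0.33 to 0.55 when 1 array was left out and was -0.0611 with each null against its own heterozygotes. Of 552 alternatives for 32 list calls, 471 kept direction and side of the threshold, 79 no longer passed and 2 reversed: primitive red cell genes, without Dll3_null replicate 2, had a mean of -0.0851 in Notch1 null against Dll3 null and 0.0324 in Dll3 null against Dll3 het, and without Dll3_null replicate 1 of 0.337 and -0.390. All 32 calls were lost with an estimated correlation, a form that uses few degrees of freedom, and 20 with fry, which asks another question. Of 3093 alternatives for named genes, 2719 were counted as the same, 367 no longer passed, 6 newly passed and 1 reversed. The reversal was Kdm5d at 0.69 in Notch1 null with sex in the fit. A change of direction was counted as the same where neither fit passed. Eif2s3y, for example, ranged from -3.31 to 0.81 in Notch1 null against wild type.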

Other observations

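The test of the genes near Dll3 was chosen after the data were seen. Stress response genes moved apart within Notch1 null. Of 36 genes of heat shock, the unfolded protein response and related stress, 7 rose and 3 fell against wild type (9 and 6 adjusted over the list alone), with a camera adjusted p of 0.121. Chac1, a glutathione-degrading enzyme induced by amino acid stress, rose 3.32-fold (log2 1.73 ± 0.17 SE) and the metallothionein gene Mt2 2.63-fold, while Hsph1, a heat shock protein, fell 1.88-fold. Among anterior Hox genes, Hoxa5 rose 1.56-fold while Hoxb5 (log2 -0.59 ± 0.10 SE) and Hoxa2 (1.48-fold) fell.

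Some craniofacial genes rose and others fell in Notch1 null, where 466 of all 12393 genes rose and 1035 fell. Of 49 genes of neural crest and face 2 rose and 7 fell (3 and 7 adjusted over the list alone), with a camera adjusted p of 0.809: Barx1, of the jaw mesenchyme, fell 2.13-fold (log2 -1.09 ± 0.15 SE), Twist1 1.55-fold and Snai1 1.52-fold, and Tfap2a rose (log2 0.58 ± 0.10). Of 21 genes of endocardial cushions and trabeculae 4 rose and 3 fell, with Has2, hyaluronan synthase, 1.73-fold and Bmp2 1.67-fold higher and a camera adjusted p of 0.111. In Dll3 null, Barx1 (log2 -0.76 ± 0.15) and Pax3 (log2 -0.88 ± 0.15) did not pass.

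The 40 measured genes nearest to Dll3 had a median log2 change of -0.03 in Dll3 null, with 0 changed. Only 1 of all 12393 genes changed in this comparison, so that count says little about this stretch of chromosome.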
